A study of Mus musculus with 10 samples.

How the data were processed

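RNA came from the myocardium of C57BL/6 mice, 5 labelled NPRA-/- and 5 labelled NPRA+/+, with 1 library per mouse number in the labels. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, strand-specific dUTP libraries were prepared, and both ends were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, cutadapt, HISAT2 and StringTie were used with the mouse build mm10; their versions, settings and the annotation are not given in the sources used here. Circular RNA, which the design text also mentions, was not analysed here.

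The deposited table holds 1 value per transcript and library, which was taken as FPKM. The table does not name its unit, and StringTie also gives TPM, which differs from FPKM by 1 factor per library; rescaling every library to the same sum was therefore among the alternatives. The values sum to 430059 to 453122 per library. Every one of the 22157 transcripts had a mean of at least 0.5 FPKM in 1 of the genotype groups. Of the 126 ways to split the 10 libraries into 5 and 5, this held in 1, the split by genotype, so the listed transcripts had been selected on these groups before deposit. Low values showed no whole-read steps, so the depth is unknown and no interval that needs it is given. Precision is given by the spread between libraries alone. Transcripts at exactly 0 numbered 1126 to 1773 per library, and 4956 transcripts were at 0 in at least 1 library, so a 0 may be a failed estimate and is described as listed at 0.

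Transcript identifiers were matched to GENCODE vM21 (GRCm38/mm10): 22107 matched, 21011 of them with the same version, and 22051 were annotated as protein-coding. FPKM of the listed transcripts of a gene symbol were summed, which gave 11777 genes; 6453 of them had 1 listed transcript, 10 symbols joined several gene identifiers, and the 50 unmatched transcripts were kept under their identifier. Positions are those of the annotation. Values were used as log2(FPKM + 1), so differences of low genes are understated. Genes and transcripts entered a test when the mean of at least 1 group was 1 FPKM or more, which left 10764 genes and 17641 transcripts.

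Genotypes were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with trend, no covariate) and Benjamini-Hochberg adjustment at 0.05. The same groups entered every comparison, 5 against 5. Single values were compared with two-sided exact permutation tests over the 126 distinct splits, whose smallest p is 0.00794. The 40 gene lists, with 943 entries, were written from textbook knowledge before the data were examined; 36 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether members move on balance one way. After adjustment fry called 0 lists (0.231 at the lowest; 4 lists at an unadjusted p under 0.05). List scores are means of log2(FPKM + 1) over members, compared per library. The genes to be named were also fixed before the data were examined: Npr1, Nppa and Nppb; the 12 largest rises and 12 largest falls past the adjusted threshold, with open places filled by the smallest unadjusted p; and up to 4 called members per list, or up to 2 with the smallest p where none was called. Predicted genes without a proper symbol were counted and not named, and 1 gene that the rule picks is not reported here.

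The tests were run on simulated data with the real means and spreads and 200 changed features. Over 10764 genes, 44% of genes changed 1.5-fold were recovered, 88% at 2-fold, 90% at 3-fold and 96% at 4-fold, and 13 of 172 calls were false. Over 17641 transcripts the shares were 24%, 44%, 58% and 56%, and 10 of 101 calls were false. The adjustment is stricter where fewer features differ, and 1 gene and 5 transcripts were called in the real data. There Clk3, with a log2 difference of 0.99 and an unadjusted limma p of 2.4e-04, had an adjusted p of 0.731. The shares hold for 200 changed features and cannot be read as the power on the real data. In the simulated gene lists a list shifted by 0.3 (log2) was called, and 0 of the 34 lists that shared no member with it. Simulated genes were drawn independently of each other, so this does not cover lists whose members move together. In the real lists the estimated correlation between members ran from -0.029 (skeletal muscle) to 0.68 (erythroid). Other splits of the real libraries, by contrast, called a median of 7 lists.

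The alternatives were pseudocounts of 0.1 and 0.5, no filter or a floor of 5 FPKM, 3 other scalings, sample weights, robust or untrended empirical Bayes, the most abundant transcript of each gene, looser thresholds, and leaving out each library in turn. Xist could not be used as a covariate because it was not among the transcripts analysed here. Other calculations and the figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.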

Results

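Messenger RNA was measured by sequencing in the myocardium of C57BL/6 mice. The design set mice with a myocardium-specific deletion of natriuretic peptide receptor A (NPRA, encoded by Npr1) against littermates that kept the receptor. NPRA is the membrane guanylyl cyclase through which atrial and B-type natriuretic peptide raise cGMP. There were 5 libraries labelled NPRA-/- (217, 227, 231, 240 and 241) and 5 labelled NPRA+/+ (228, 230, 242, 243 and 255). The deposited table gave one value per transcript and library for 22157 transcripts, which belonged to 11777 genes. The values summed to between 430059 and 453122 FPKM per library, and the sequencing depth is unknown. Mitochondrially encoded transcripts made up 28.4% ± 1.35 of this sum in the libraries labelled NPRA-/- and 27.8% ± 0.646 in those labelled NPRA+/+ (mean ± SD, n = 5 each; two-sided exact permutation p = 0.389). The median transcript was at 2.42 ± 0.0449 FPKM in the libraries labelled NPRA-/- and at 2.51 ± 0.0391 FPKM in those labelled NPRA+/+ (exact permutation p = 0.0159, not adjusted over the 5 measures per library). The sum (exact permutation p = 0.452), the share of the 10 most abundant transcripts (exact permutation p = 0.310) and the number of transcripts at 0 (exact permutation p = 0.151) did not pass this test. The Y-linked gene Ddx3y was present in all 10 libraries, at 12.9 to 19.3 FPKM.

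The deleted gene itself was examined first. Npr1 (chromosome 3, 90450591 to 90465866, minus strand, GRCm38/mm10; 1 listed transcript) stood at 4.64 ± 0.492 FPKM in the libraries labelled NPRA-/- and at 4.68 ± 0.301 FPKM in those labelled NPRA+/+ (SD, n = 5 each). The log2 difference was -0.013, and the two-sided exact permutation test gave p = 0.857. The 10 libraries lay between 4.12 and 5.20 FPKM, so Npr1 mRNA did not separate the genotypes and did not check the labels. The deleted part of Npr1 is not given in the sources used here, and 1 value per transcript cannot show the loss of single exons. Directions given from here on are therefore those of libraries labelled NPRA-/- relative to libraries labelled NPRA+/+.

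The 2 ligands of the receptor did not differ beyond the spread between libraries either. Nppa, which encodes atrial natriuretic peptide (chromosome 4, 148000722 to 148002079), was at 381 ± 54.9 FPKM in libraries labelled NPRA-/- and 433 ± 221 FPKM in libraries labelled NPRA+/+ (SD, n = 5 each; exact permutation p = 0.849). Nppb, which encodes B-type natriuretic peptide (chromosome 4, 147985788 to 147987205), was at 168 ± 17.8 and 156 ± 77.8 FPKM, respectively (exact permutation p = 0.619). The wide spread of the NPRA+/+ group came from replicate 243, with 804 FPKM of Nppa and 269 FPKM of Nppb, and from replicate 255, with 236 and 51.7 FPKM. Of 19 measured genes of natriuretic peptide and cGMP signalling, 7 were higher and 12 lower, and none passed the test. The other receptors of the family, Npr2 (log2 difference -0.43, SE 0.26) and the clearance receptor Npr3 (3.46 ± 1.38 against 4.73 ± 0.989 FPKM), had the smallest p-values of that list, with adjusted p of 0.908 and 0.906; the log2 difference of Npr2 was -0.28 without replicate 240, and that of Npr3 went from -0.42 to -0.18 without replicate 217. The hypertrophy and fetal gene programme had 18 measured members, of which 7 were higher and 11 lower, and none passed. In that list Enah was at 25.4 ± 0.961 against 28.7 ± 3.82 FPKM and Mybpc2 at 5.10 ± 0.650 against 7.07 ± 3.31 FPKM. In replicate 243 Enah was at 34.2 FPKM and Mybpc2 at 12.2 FPKM. Without that library the log2 difference went from -0.16 to -0.099 for Enah. It went from -0.32 to -0.12 for Mybpc2, which rested largely on replicate 243.

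**Figure D1:**
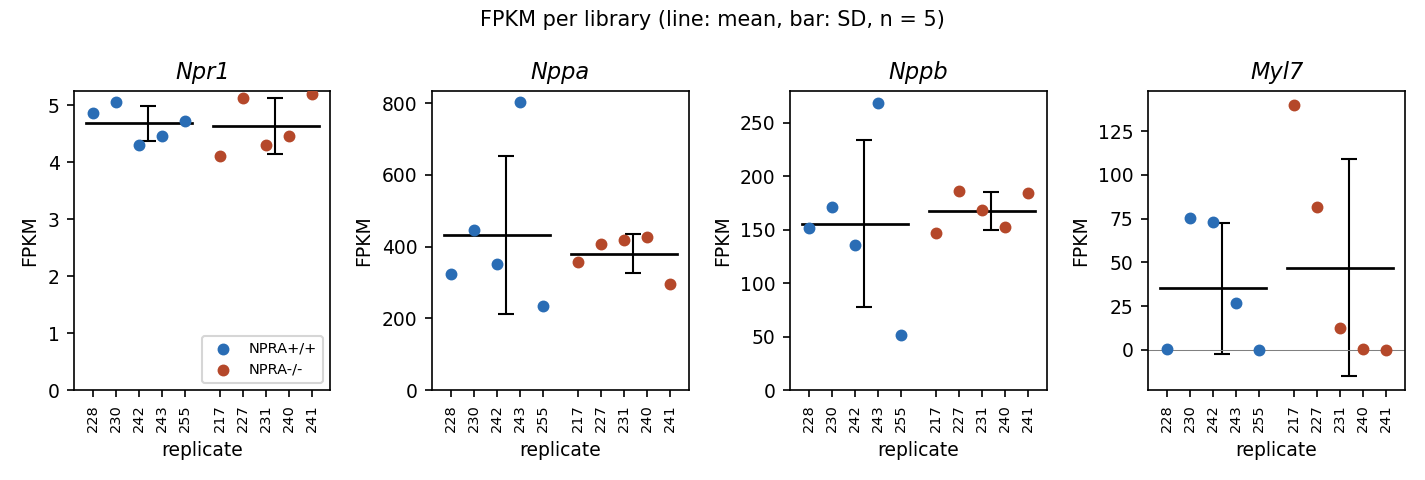
FPKM (vertical axes) of Npr1, Nppa, Nppb and the atrial myosin light chain Myl7 in each library (horizontal axes, replicate number; blue, NPRA+/+; red, NPRA-/-), with the mean of each group of 5 as a line and the SD as a bar. The 10 values of Npr1 lie between 4.12 and 5.20 FPKM in both genotypes, while Myl7 runs from 0 to 140 FPKM among libraries labelled NPRA-/- and from 0 to 75.4 FPKM among those labelled NPRA+/+.

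Expression of whole genes was compared next, to find which mRNAs differed with genotype. Eapp, which encodes the E2F-associated phosphoprotein (chromosome 12, 54670340 to 54695897), fell from 27.1 ± 2.95 FPKM in libraries labelled NPRA+/+ to 16.0 ± 1.22 FPKM in libraries labelled NPRA-/- (SD, n = 5 each). Its log2 difference was -0.73 (SE 0.085), it was lower in 5 of 5 libraries without overlap between the groups, and its limma adjusted p was 0.0368. Eapp was the 1 gene of 10764 tested that passed the adjusted threshold. At an unadjusted p under 0.05 there were 594 genes, 149 higher and 445 lower, where 538 were expected by chance. With median-of-ratios scaling the same threshold gave 271 higher and 294 lower genes, and with quantile normalization 267 and 275. With values rescaled to the same sum it gave 121 higher and 497 lower genes. The excess of lower genes thus depended on the scaling. Median-of-ratios scaling and quantile normalization bring the typical difference near 0 by construction (medians 0.0015 and -2.1e-04). Their even counts therefore cannot show that the excess was false. Eapp did not pass with median-of-ratios scaling or quantile normalization (limma adjusted p = 0.0927 and 0.0724, respectively) or without trend (0.0739). Over 21 alternatives it passed in 9. The call of Eapp was lost when any of 8 libraries was left out, and remained only without replicate 217 (adjusted p = 0.0264) or without replicate 243 (adjusted p = 0.00294); over the 10 fits it ranged from 0.00294 to 0.188, while the log2 difference stayed between -0.80 and -0.70.

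The following genes had the smallest unadjusted p-values in each direction, and none of them but Eapp passed the adjusted test. Among the 12 with higher values, Clk3, a kinase of SR splicing proteins, was at 9.16 ± 1.83 FPKM in libraries labelled NPRA-/- and 4.19 ± 1.41 FPKM in libraries labelled NPRA+/+ (limma log2 difference 0.99, SE 0.19, adjusted p = 0.731). The splicing factor Srsf4 (chromosome 4, 131873617 to 131901706) was at 24.1 to 29.4 FPKM in all 5 libraries labelled NPRA-/-. In 4 libraries labelled NPRA+/+ it was at 3.64 to 4.79 FPKM, and in replicate 242 of that group it was at 25.9 FPKM. Its log2 difference was 1.96 (SE 0.41, limma adjusted p = 0.807) over all 10 libraries and 2.43 (limma adjusted p = 1.29e-06) without replicate 242. The second fit leaves out the 1 library that goes against the split, so its p is no test of genotype. Srsf4 had 1 listed transcript, so a shift of reads to transcripts not listed cannot be told apart. Also among them were Shmt1, the cytosolic serine hydroxymethyltransferase (2.63 ± 0.158 against 1.73 ± 0.246 FPKM), Atp5a1, the alpha subunit of ATP synthase (658 ± 33.5 against 575 ± 24.4 FPKM), Cox6b2, a subunit of cytochrome c oxidase (5.81 ± 1.12 against 3.15 ± 1.00 FPKM), and Nagk, which phosphorylates N-acetylglucosamine (log2 difference 0.39, SE 0.097). The others were the cation channel gene Trpm4 (1.87 ± 0.154 against 0.847 ± 0.386 FPKM), the kinase gene Pnck, Rhobtb1, Dcun1d2 (23.4 ± 11.5 against 8.86 ± 1.63 FPKM), the deubiquitinase gene Usp14 (16.5 ± 1.16 against 13.6 ± 1.00 FPKM) and the linker histone gene Hist1h1e.

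Among the 12 genes with lower values, next to Eapp, were Tfpi, an inhibitor of blood coagulation (19.2 ± 2.99 against 35.3 ± 8.05 FPKM; log2 difference -0.83, SE 0.16), Hdac7, a class II histone deacetylase (log2 difference -1.11, SE 0.25), and Lox, the lysyl oxidase that crosslinks collagen (1.22 ± 0.163 against 2.06 ± 0.356 FPKM). Spns2, a sphingosine-1-phosphate transporter, was at 1.75 ± 0.801 against 3.41 ± 0.272 FPKM. Dock9 was at 7.61 ± 0.875 against 10.6 ± 1.22 FPKM and the transcription factor gene Elf1 at 4.33 ± 0.486 against 5.86 ± 0.451 FPKM. Fam20a, which encodes a protein of the secretory pathway, was listed at 0 to 0.037 FPKM in 4 libraries labelled NPRA-/- and at 1.37 FPKM in replicate 217, against 1.49 to 2.64 FPKM in libraries labelled NPRA+/+. Its adjusted p was 0.731 over all libraries and 0.0125 without replicate 217 (limma). Replicate 217 was the 1 library of its group near the values of the other group, so the second p is no test of genotype. The remaining genes were Bend7, Pir, Zfp710 and Zfp219. In 21 of these 24 genes the libraries of the genotypes did not overlap, which chance gives at a share of 0.00794 per gene, but the genes were picked for small p-values.

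Single transcripts were compared in order to find genes whose isoforms moved apart. The listed transcript ENSMUST00000110713.9 of Eapp (chromosome 12, 54673466 to 54695821) was listed at 0 in all 5 libraries labelled NPRA-/- and lay between 11.2 and 15.1 FPKM in the 5 labelled NPRA+/+ (limma adjusted p = 1.28e-07). Usp14, which encodes a deubiquitinase of the proteasome (chromosome 18), had 2 listed transcripts, and both were called. Its transcript ENSMUST00000116669.1 was listed at 0 in all 5 libraries labelled NPRA+/+ and lay between 6.80 and 9.86 FPKM in those labelled NPRA-/- (adjusted p = 5.10e-07, limma). Its other listed transcript, ENSMUST00000092096.12, fell from 13.6 ± 1.00 to 8.11 ± 0.785 FPKM (SD, n = 5 each; limma log2 difference -0.69, SE 0.082, adjusted p = 0.0360). Sbno1, a homolog of strawberry notch (chromosome 5), had its transcript ENSMUST00000065263.11 at 1.59 to 9.55 FPKM in libraries labelled NPRA-/- and at 0 in 4 libraries labelled NPRA+/+, with 0.0016 FPKM in the other, replicate 243 (limma adjusted p = 0.0368). Sulf1, an extracellular sulfatase that acts on heparan sulfate (chromosome 1), had its transcript ENSMUST00000180062.7 listed at 0 in the 5 libraries labelled NPRA-/- and at 1.95 to 8.26 FPKM in the others (limma adjusted p = 0.0211).

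These 5 transcripts, 2 higher and 3 lower, were all that passed of 17641 tested. The sum over all listed transcripts of Sbno1 was 16.4 ± 1.87 against 16.0 ± 0.445 FPKM (exact permutation p = 0.690, n = 5 each) and that of Sulf1 6.33 ± 1.23 against 7.18 ± 2.30 FPKM (exact permutation p = 0.603). For Usp14 and for Eapp the sums of the genotypes did not overlap (exact permutation p = 0.00794 each, the smallest that 5 against 5 libraries can give). At an unadjusted p under 0.05 there were 971 transcripts, where 882 were expected by chance. Leaving out 1 library gave between 2 transcripts (without replicate 243) and 10 (without replicate 230), with 3 without replicate 228 and 9 without replicate 227 or 241.

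**Figure D2:**
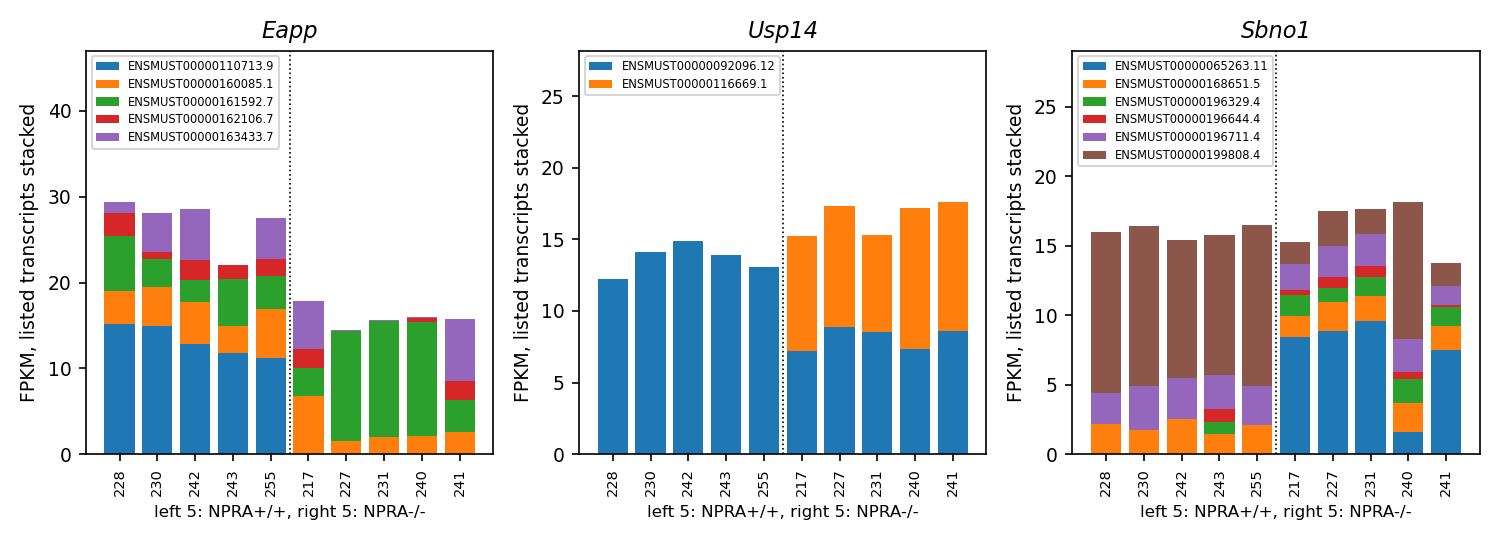
FPKM of the listed transcripts of Eapp, Usp14 and Sbno1, stacked per library (bars; replicate numbers below, with the 5 NPRA+/+ libraries to the left of the dotted line and the 5 NPRA-/- libraries to the right). The transcript ENSMUST00000110713.9 of Eapp is at 0 in all 5 libraries labelled NPRA-/-, while ENSMUST00000116669.1 of Usp14 is at 0 in all 5 labelled NPRA+/+.

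Metabolic genes were compared as lists, since the title of the series names metabolism. Fatty acid beta-oxidation was the most uniform of them: 25 of its 26 measured genes were higher in libraries labelled NPRA-/-, with a median log2 difference of 0.064 (0.049 without replicate 230 to 0.11 without replicate 255). The 25 include the acetyl-CoA carboxylase genes, which do not encode enzymes of the oxidation itself. Acadm, the medium-chain acyl-CoA dehydrogenase, was at 635 ± 17.9 against 589 ± 33.5 FPKM, and Hadhb, of the trifunctional protein, at 228 ± 10.9 against 211 ± 12.1 FPKM (SD, n = 5 each). The list score was above the NPRA+/+ mean in 5 of 5 libraries, at 6.60 to 6.74, but the groups overlapped: replicate 255, labelled NPRA+/+, had the highest score of all 10 libraries (6.75), and the other 4 of its group were at 6.51 to 6.60. Replicate 255 also stood apart in Ucp1 and in the PPAR target score. Camera with a preset correlation gave an adjusted p of 9.98e-08, and the adjusted p was 0.405 with an estimated correlation. The exact permutation test of the score per library gave p = 0.230.

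The TCA cycle had 14 of 20 genes higher, with Idh2 at 632 ± 23.8 against 574 ± 28.0 FPKM and Suclg1 at 233 ± 7.07 against 221 ± 9.16 FPKM. The nuclear-encoded respiratory chain had 52 of 75 genes higher, with Atp5a1 above and Cox5b at 676 ± 32.7 against 630 ± 19.5 FPKM. Of the mitochondrially encoded respiratory chain, 12 of 13 genes were higher, led by mt-Atp6 (9745 ± 534 against 9185 ± 420 FPKM). PPAR target genes had 15 of 21 genes higher, among them Mlycd (28.5 ± 2.61 against 24.6 ± 4.51 FPKM). Mlycd, Acadm and further genes are in both the PPAR and the beta-oxidation list. Sdha to Sdhd are in both the TCA cycle and the nuclear-encoded respiratory chain list. The metabolic lists are therefore not independent of each other. Amino acid, ketone and one-carbon metabolism had 18 of 28 higher, and Shmt1 was its 1 gene that passed when adjusted over the list alone. Glycolysis and glucose use had 20 of 32 higher, with Pdk1 at 26.5 ± 1.70 against 23.4 ± 1.52 FPKM but Eno1 at 73.9 ± 2.71 against 83.3 ± 6.11 FPKM. The adult sarcomere list had 15 of 21 higher, with Myom2 at 337 ± 31.6 against 299 ± 21.9 FPKM and Tnnt2 at 8023 ± 566 against 7455 ± 380 FPKM. These 7 lists had medians between 0.013 and 0.060 and camera adjusted p between 1.53e-04 and 0.0321. Their adjusted p lay between 0.363 and 0.602 with an estimated correlation, and no member of any of them passed over all genes. Their list scores were above the NPRA+/+ mean in 2 of 5 libraries labelled NPRA-/- for the nuclear-encoded respiratory chain, in 3 of 5 for the TCA cycle and PPAR targets and in 4 of 5 for the other 4, with overlap between the groups in all 7 (exact permutation p of the scores 0.127 to 0.786). When 1 library was left out, the median ran from -0.0048 (without replicate 217) to 0.041 for the nuclear-encoded respiratory chain, from 0.0042 (without 230) to 0.031 for the TCA cycle, from 0.015 (without 243) to 0.12 (without 255) for PPAR targets and from 0.0033 (without 217) to 0.033 for glycolysis. It ran from 0.018 to 0.080 (without 227) for the mitochondrially encoded list, from 0.010 (without 230) to 0.045 for amino acids and from 0.014 to 0.049 (without 240) for the sarcomere. All 7 calls ended without replicate 217 and without replicate 230, and those of the amino acid, PPAR and glycolysis lists also without replicate 243; the PPAR list also lost its call without replicate 228 or 241, glycolysis without 227 or 241, and the mitochondrially encoded list without 231, 241 or 255.

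Genes of stromal and immune cells were lower as lists in libraries labelled NPRA-/-. All 33 measured genes of extracellular matrix and fibrosis were lower, with a median log2 difference of -0.20 (-0.26 without replicate 242 to -0.12 without replicate 230). Lox and Col5a2 (4.68 ± 0.404 against 6.69 ± 1.19 FPKM) passed when adjusted over the list alone, and none passed over all genes. Of 17 fibroblast genes 16 were lower (median -0.17, and -0.25 to -0.12 without 1 library), with Fbln1 at 19.8 ± 1.65 against 23.5 ± 2.87 FPKM and Col1a1 with a log2 difference of -0.44 (SE 0.17). Of 20 macrophage and monocyte genes 18 were lower (median -0.17, and -0.21 to -0.14 without 1 library), with C1qb at 35.0 ± 2.80 against 41.5 ± 3.49 FPKM and Ms4a7 at 0.373 ± 0.460 against 1.41 ± 0.860 FPKM. Of 17 endothelial genes 16 were lower (median -0.14), with Esam at 24.0 ± 1.95 against 32.3 ± 5.61 FPKM and Pecam1 at 51.0 ± 4.39 against 56.4 ± 1.22 FPKM (log2 difference -0.15, and -0.095 without replicate 217). Smooth muscle and pericyte genes were lower in 14 of 15, with Tagln at 11.5 ± 1.42 against 16.5 ± 3.59 FPKM, and endocardial and valve genes in 9 of 9, with Edn1 at 1.81 ± 0.153 against 2.16 ± 0.237 FPKM. The inflammatory and NF-kB list had 12 of 14 lower, with S100a9 at 1.98 ± 0.904 against 3.93 ± 1.02 FPKM, and the interferon list 19 of 27, with Oasl2 at 2.33 ± 1.57 against 4.76 ± 0.909 FPKM.

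Camera with a preset correlation gave adjusted p of 2.05e-07 for the matrix list, 2.94e-05 for fibroblasts, 7.34e-05 for macrophages, 0.00881 for endothelium, 0.0108 for smooth muscle, 0.0138 for endocardium, 0.0395 for the inflammatory and 0.0417 for the interferon list. Together with the 8 lists that were higher, 16 of 36 lists passed this test, and 0 passed with an estimated correlation (adjusted p = 0.363 at the lowest; 4 lists at an unadjusted p under 0.05). The list scores per library, tested by exact permutation, gave p = 0.00794 for the inflammatory list, 0.0159 each for the endothelial and macrophage lists and 0.0397 for the smooth muscle list, but 0.127 for the matrix, 0.0556 for the fibroblast, 0.183 for the endocardial and 0.381 for the interferon list, and none of the 36 passed after Benjamini-Hochberg adjustment (0.190 at the lowest). The score was below the NPRA+/+ mean in 4 of 5 libraries labelled NPRA-/- for the endocardial and interferon lists and in 5 of 5 for the other 6 lower lists, and the groups overlapped in all of these 8 but the inflammatory list. The number of lists called fell to 4 without replicate 217 and to 6 without replicate 230. The lists of extracellular matrix, fibroblasts, macrophages and fatty acid beta-oxidation were called in all 10 such fits. In the matrix list, replicates 230 and 243 of the NPRA+/+ group had the highest scores (4.18 and 3.96). The rest of that group, at 3.56 to 3.64, lay within the range of libraries labelled NPRA-/- (3.36 to 3.74). Fibroblast scores were 4.87 and 4.82 in these replicates and 4.56 to 4.57 in the rest, against 4.35 to 4.64. Beta-oxidation scores were lowest in the same replicates, at 6.51 each. No fit left out both, so how far these lists rest on them is not shown. The interferon list lost its call without replicate 217, 227, 231, 242, 243 or 255 (median -0.29 to -0.060 over the 10 fits) and the inflammatory list without 217, 228, 230, 241 or 243 (-0.19 to -0.091). The endocardial list lost it without 217, 230 or 243 (-0.36 to -0.17), the smooth muscle list without 217 or 230 (-0.15 to -0.058) and the endothelial list without 217 (-0.15 to -0.10).

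**Figure D3:**
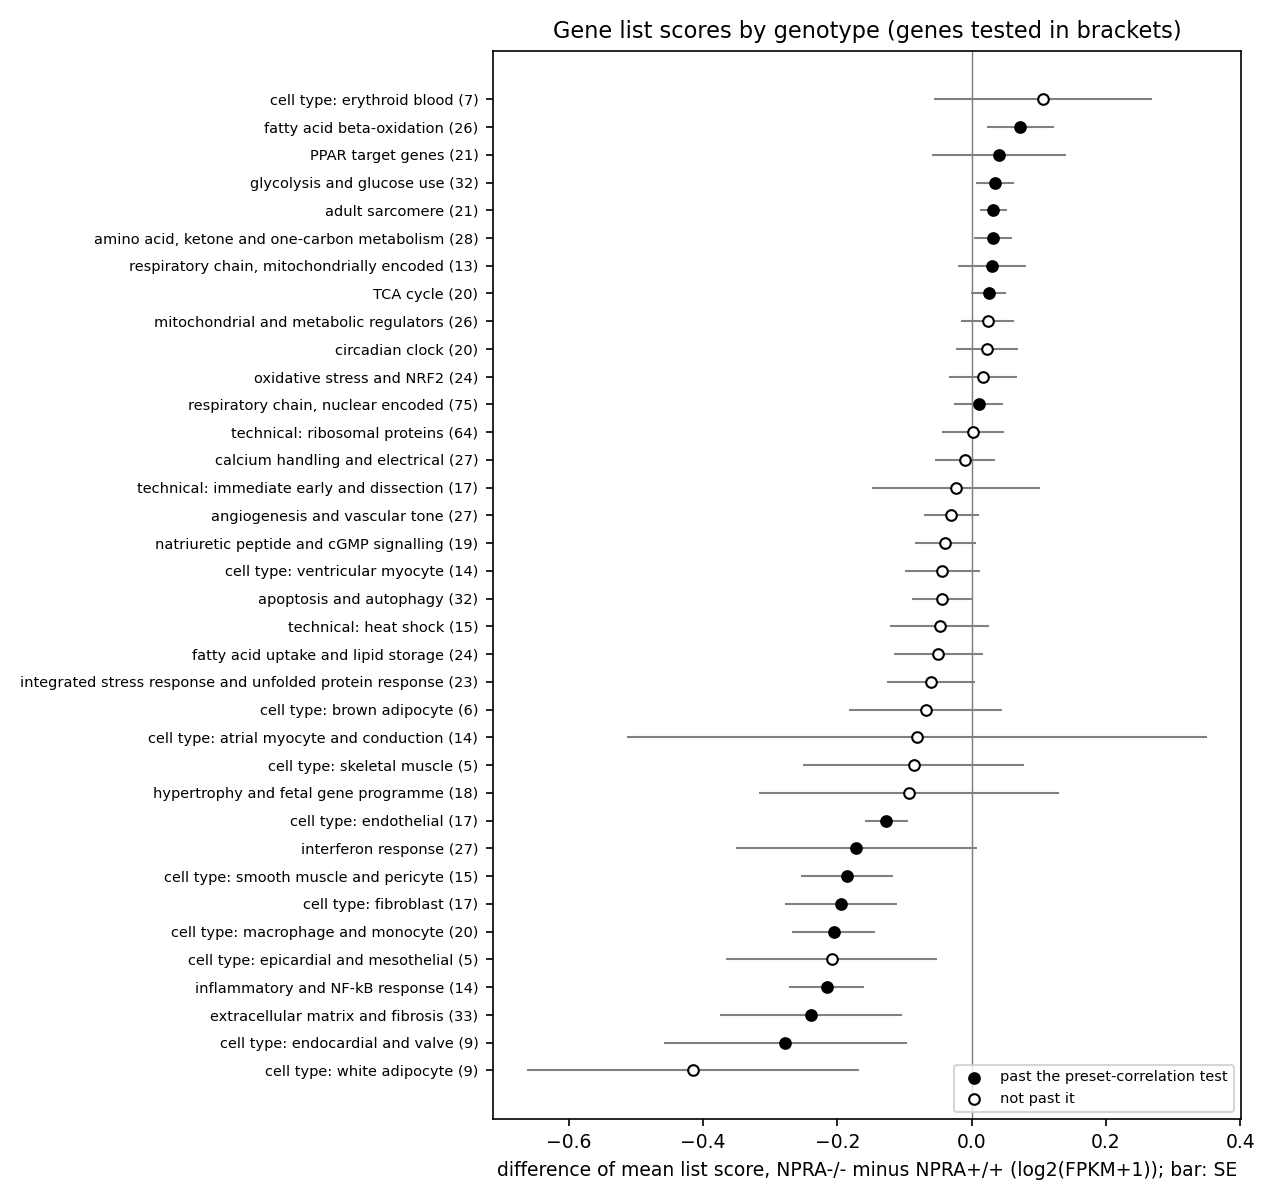
Difference between the genotypes (NPRA-/- minus NPRA+/+) in the mean log2(FPKM + 1) of each of 36 gene lists (horizontal axis; bars, standard error from 5 and 5 libraries; number of genes in brackets), with filled points for lists past the camera test with a preset correlation. Fatty acid beta-oxidation lies at 0.073 and extracellular matrix and fibrosis at -0.24.

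The other lists did not pass over all 10 libraries. Genes of white adipocytes were lower in 7 of 9 (camera adjusted p = 0.0618), with Cidec at 0.234 ± 0.241 against 1.46 ± 1.35 FPKM and Scd1 at 5.83 ± 1.87 against 10.2 ± 5.70 FPKM. Scd1 was at 19.5 FPKM in replicate 255, without which its log2 difference went from -0.63 to -0.38, and the median of the white adipocyte list ran from -0.77 (without 227) to -0.21 (without 255), with a call without 227 or 228. All 5 measured epicardial genes were lower (adjusted p = 0.0618), and of these C3 (23.0 ± 2.51 against 30.9 ± 5.66 FPKM) passed when adjusted over the list alone. Erythroid genes were higher in 6 of 7 (adjusted p = 0.0618), and the list was called in 5 of the 10 fits that left out 1 library (without 227, 231, 242, 243 or 255; median 0.034 to 0.25, adjusted p 0.00302 to 0.577). Regulators of mitochondria and metabolism were higher in 14 of 26 (adjusted p = 0.0528) and called without 231, 228 or 255, ribosomal proteins without 240, 241, 242 or 243, and the epicardial list in 2 of the 6 fits that kept 5 measured genes (without 241 or 255). The clock (without 227), stress response (without 240), oxidative stress (without 242), hypertrophy and fatty acid uptake lists (each without 255) were called in 1 of these fits. The circadian clock had 14 of 20 genes higher (adjusted p = 0.0893), the integrated stress and unfolded protein response 18 of 23 lower (0.314), and oxidative stress and NRF2 12 of 24 higher (0.218). Adjusted p for calcium handling was 0.445, for brown adipocytes 0.465, for fatty acid uptake and lipid storage 0.619, for skeletal muscle 0.784, and for angiogenesis, atrial myocytes and natriuretic peptide signalling 0.914 each. For apoptosis and autophagy and for ventricular myocytes camera p was 0.389 and 0.381 before adjustment. The hypertrophy list and the immediate early list each had an adjusted p of 0.887, ribosomal proteins 0.167 and heat shock genes 0.989. Mean and median differed in sign for calcium handling, apoptosis, ventricular, skeletal muscle, brown adipocyte, immediate early and oxidative stress genes, and camera placed heat shock and fatty acid uptake genes on the higher side although their mean and median were below 0. No lymphocyte gene was measured; 4 neutrophil and mast cell genes, of which S100a9 passed when adjusted over the list alone, 3 Schwann and neuronal genes and 4 sex-linked genes were too few for a set test.

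Libraries did not group by genotype in their overall profile. The first principal component carried 15.5% of the variance (exact permutation p = 0.929 against genotype, n = 5 each), the second 13.2% (exact permutation p = 0.0714) and the third 12.1% (exact permutation p = 0.262). Correlations between libraries were 0.971 to 0.977 within a genotype and 0.971 to 0.979 between genotypes, and 5 of the 10 libraries were closer to their own genotype.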

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

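The tests on transcripts near 0 in 1 genotype, on scaling and on the share of other cells, and the test for swapped labels, were chosen only after the results were seen; the counts over other splits of the libraries and the relation of Npr1 to endothelial genes were set before their results were seen.

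Single libraries stood far from the other 4 of their group in 30 of 284 groups examined, over 142 genes, list scores and library measures. The figure given for each is its gap to the nearest library divided by the range of the group, with a limit of 0.71. Chance would give about 14.2 for independent, normally distributed values. FPKM were used untransformed and list scores contain some of the genes, so an excess over 14.2 is not established. Replicate 255, labelled NPRA+/+, had the most, with 6. Its brown fat gene Ucp1 was at 5.89 FPKM (0.985) against at most 0.090 FPKM in the other 4, and Lipe (0.821), Mlycd (0.760), the brown adipocyte score (0.864) and the PPAR target score (0.848) were high, while the Schwann and neuronal score was low (0.721). In replicate 242, labelled NPRA+/+, Srsf4 (0.949), Trpm4 (0.806) and Dusp1 (0.720) were high and Mfn2 (0.777) and the smooth muscle score (0.778) low. The other libraries labelled NPRA+/+ had a low Eapp (0.753) and a high ribosomal protein score (0.711) in replicate 243, a high S100a9 (0.721) and Nr2f2 (0.749) in replicate 228, and a high Fbln1 (0.807) in replicate 230. Among libraries labelled NPRA-/-, replicate 217 had high Fam20a (0.973) and Enah (0.793) and low Elf1 (0.754) and skeletal muscle score (0.906). Replicate 227 had a high Pir (0.777), low mt-Nd2 (0.879) and Esam (0.770), and the lowest share of the 10 most abundant transcripts (0.740). Replicate 240 had a low Cox8b (0.735) and Myl3 (0.784) and a high stress response score (0.754), replicate 241 a high Bckdk (0.714) and a low Ifi27l2a (0.750), and replicate 231 a low apoptosis score (0.847).

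The counts of the model fits were set against 100 of the 126 splits of the 10 libraries into 5 and 5, the labelled one included. At least 1 gene passed the adjusted threshold in 32 of these 100 splits, with 3 genes in the highest other split. The labelled split had 594 genes at an unadjusted p under 0.05, and 28 splits had as many, up to 738. It had 5 transcripts past the threshold, and 11 splits had as many, up to 9. Chance was not excluded for any of these counts.

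The first pattern is the set of transcripts that were under 0.05 FPKM in all libraries of 1 genotype and at 0.5 FPKM or more in all of the other, which held for 6 transcripts, of Eapp, Sbno1, Sulf1, Usp14, Usp5 and Zfp65. As many were found in 4 of the 126 splits, with 9 in the highest other split, and from 1 FPKM upward, where the selection of the table cannot favour the labelled split, 4 transcripts and 2 of 126 splits, with 4 in the highest other (under 0.1 FPKM instead, 6 and 2 of 126 splits, with 9 and 4 in the highest other); the pattern and these 4 pairs of limits were taken from the labelled split, so the counts cannot exclude chance, and 1183 of 10314 transcripts that reach 5 FPKM were under 0.05 FPKM in another library. For the 5 genes other than Eapp, the other listed transcripts made up a median of 85.4% of the missing value (65.7% to 117%), which is consistent with reads moved between isoforms by the abundance estimate, or with a true isoform switch. The sum of Usp14, 1 of these 5 genes, differed without overlap between the genotypes (exact permutation p = 0.00794). For Eapp the other listed transcripts made up 15.3%, and its sum did not overlap between the genotypes either. The 15.3% is a net value: ENSMUST00000161592.7 was higher in libraries labelled NPRA-/- (mean 9.32 against 4.27 FPKM), and the others were lower on average. In replicates 227, 231 and 240 it was at 12.8 to 13.5 FPKM, and ENSMUST00000163433.7 was at 0.140 to 0.168 FPKM. In replicates 217 and 241 these transcripts were at 3.24 and 3.70 FPKM and at 5.66 and 7.19 FPKM, respectively. A move between transcripts of like length would keep the sum, so it does not account for the whole difference of Usp14 or Eapp. FPKM is divided by transcript length, and a move to a transcript of another length changes the sum. Lengths were not compared, so such a move stays open, as do transcripts that are not listed. A strain difference carried along with the targeted locus is argued against for these 6 only, since 0 of them lie on the chromosome of Npr1. It stays open for the transcript ENSMUST00000107266.7 of Pogz, which lies on that chromosome (94837713 to 94880332) and narrowly missed the limits. This transcript was at 1.45 to 2.84 FPKM in libraries labelled NPRA-/- (limma adjusted p = 0.0858). Among libraries labelled NPRA+/+ it was at 0 in 4 and at 0.641 FPKM in replicate 255. A difference elsewhere in the genome, or an effect of the deletion, was not tested.

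The second pattern is the lower level of stromal and immune lists in libraries labelled NPRA-/-. With 16 lists called in the labelled split, 9 of 100 splits had as many, up to 19 and with a median of 7 in the other splits, so chance is not excluded. The median transcript was also lower (2.42 against 2.51 FPKM, exact permutation p = 0.0159). For the extracellular matrix list, a scaling difference of 1 factor per library is argued against as the whole cause. The median of that list was still -0.17 after median-of-ratios scaling, which moved the median of all genes only from -0.029 to 0.0015. The other stromal and immune lists were not examined in this way. A lower share of RNA from cells other than cardiomyocytes may contribute: the scores of 6 lists of resident cells (82 genes, 13 of them also in another list) were all lower, and none of 15 pairs of these lists differed (smallest adjusted exact p = 0.978), which with 5 libraries each does not show that they fell alike. An effect of the deletion on these cells remains open and was not tested.

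The third pattern is that Npr1 was not lower in libraries labelled NPRA-/-. Labels swapped between the groups can be neither supported nor excluded by Npr1: the lowest library had 0.897 of the median of all 10, and with no low library right and swapped labels look alike. Npr1 mRNA from cells outside the deletion may be a source, but Npr1 and the endothelial score were not clearly related (r = 0.27 within genotype, exact permutation p = 0.491; rho = 0.36, p = 0.373, n = 10; r = -0.032 without replicates 217 and 255), so this cannot be told apart from a transcript that lost only part of its exons. That the deletion is absent from some or all of the libraries also stays open.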

How the results depend on the processing

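The restriction to genes with 1 listed transcript or to transcripts above 0 in all libraries, the fold filter on transcripts and the permutation of list scores were chosen after seeing the data; the other settings were fixed before the data were examined. Covariate Xist was not run, since it had no value, and tests on counts did not apply. Where no cause is named, the cause was not tested. Depth is unknown, so its effect cannot be given.

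The number of genes past the adjusted threshold was 1 with pseudocounts of 0.1 and 0.5, without a filter, with a floor of 5 FPKM, with values rescaled to the same sum, with sample weights, with robust empirical Bayes and at an adjusted p under 0.1. It was 0 with quantile normalization (542 genes at an unadjusted p under 0.05), with median-of-ratios scaling (565), without trend (616) and over genes with 1 listed transcript (309), a set that leaves Eapp out, and 2 with the most abundant transcript of each gene, which were Sulf1 and Usp14. An unadjusted p under 0.05 with a 1.5-fold difference gave 75. Leaving out 1 library gave 0 to 2; without replicates 231, 240, 241, 228 and 230 it was 0, without 217 it was 2 (Eapp and Fam20a), and without 227, 242, 243 and 255 it was 1, which was Eapp only without 243. Genes at an unadjusted p under 0.05 were 594 over all; a floor of 5 FPKM (372) and genes with 1 listed transcript (309) tested fewer genes, and leaving out 1 library gave 471 to 655. Over 21 alternatives in which Eapp was tested, its adjusted p ranged from 0.00294 to 0.909 and was under 0.05 in 9.

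Transcripts past the threshold were 5 with a pseudocount of 0.1 and without a filter, 0 of 15099 above 0 in all libraries (795 at an unadjusted p under 0.05 in limma; this filter by its construction leaves out 4 of the 5, which are at 0 in some libraries), 489 at an unadjusted p under 0.05 with a 1.5-fold difference, and 2 (without replicate 243) to 10 (without 230) when 1 library was left out. Lists called with the preset correlation were 16 with a pseudocount of 0.1, 19 with median-of-ratios scaling, 8 over genes with 1 listed transcript, 0 with an estimated correlation (4 at an unadjusted p under 0.05), 0 by permutation of scores (4 unadjusted) and 4 (without replicate 217; 6 without 230) to 19 when 1 library was left out, with 4 of the 16 lists called in all 10 of these fits and 10 of the 20 other lists called in some. The components of sample structure stayed above 0.05 without the sex-linked, erythroid, adipocyte and immediate early lists (0.992, 0.0794 and 0.254).

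The log2 difference of Npr1 was 0.026 with quantile normalization and 0.016 with median-of-ratios scaling, and -0.048 to 0.021 without 1 library. With the most abundant transcript the direction turned for Cox6b2 (-0.063), Nagk (-0.040), Usp14 (-0.69), Eapp (0.82), Zfp710 (0.045), Zfp219 (1.59), Cacnb2 (-0.24), Bckdk (-0.037), Esam (0.053) and Hspa8 (-0.097), since it follows 1 isoform. Without 1 library, Nppa ranged from -0.25 to 0.19, Nppb from -0.071 to 0.52 and Neb from -0.32 to 0.077. Median differences of lists whose camera direction turned without 1 library ranged from -0.060 to 0.0059 for angiogenesis, -0.069 to -0.0093 for heat shock, -0.033 to 0.029 for ribosomal proteins, -0.11 to 0.033 for immediate early genes, -0.076 to -0.015 for natriuretic peptide signalling, -0.12 to 0.024 for hypertrophy, -0.22 to 0.043 for atrial myocytes, -0.031 to 0.046 for fatty acid uptake, -0.048 to 0.072 for brown adipocytes, -0.053 to 0.034 for ventricular myocytes, -0.24 to 0.047 for skeletal muscle and -0.015 to 0.042 for calcium handling; none of these lists was called over all libraries. Over genes with 1 listed transcript the camera direction turned for natriuretic peptide signalling (0.0043), hypertrophy (-0.025), apoptosis (-0.061), angiogenesis (-3.2e-04) and ventricular myocytes (-0.060), and with median-of-ratios scaling for immediate early genes (0.046). Camera sets a list against the other genes, so its direction can turn while the median keeps its sign, as it did for hypertrophy, angiogenesis and immediate early genes in these settings. Of 2024 values of 96 named genes under the alternatives, 1997 kept their direction and their side of the threshold. Of these genes only Eapp passed over all 10 libraries, so for the others the count mostly shows that they stayed short of the threshold.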

Other observations

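The relations between scores and the test around Npr1 were set before their results were seen; the genes Myl7, Myl4, Sln and Dkk3 and the gene Son were chosen after their values were seen. Libraries of both genotypes differed widely in genes of the atrial myocardium. Myl7, the atrial regulatory light chain, was at 140 FPKM in replicate 217 and 81.8 in replicate 227, at 75.4 and 73.2 in replicates 230 and 242, at 26.9 and 12.7 in replicates 243 and 231, and at 0.586 FPKM or less in the other 4. Myl4, the atrial essential light chain, ran from 1.58 FPKM in replicate 255 to 138 FPKM in replicate 217. Sln, which encodes sarcolipin, ran from 0 to 18.2 FPKM, and Dkk3 from 0.924 to 16.7 FPKM. None of the 4 separated the genotypes (two-sided exact permutation p = 0.968 for Myl7, 0.913 for Myl4, 0.976 for Sln and 0.722 for Dkk3, n = 5 each). Son, which encodes a splicing cofactor (chromosome 16, 91647506 to 91679221), was at 16.8 to 19.3 FPKM in 4 libraries labelled NPRA-/-. It was at 39.7 FPKM in replicate 227 of that group and at 32.7 to 40.9 FPKM in the 5 labelled NPRA+/+. Without replicate 227 its log2 difference was -1.04 (limma adjusted p = 0.00106). That fit leaves out the 1 library that goes against the split, so its p is no test of genotype.

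A hypothesis was that the spread of Nppa between libraries follows their atrial content. Within genotype, log2 Nppa and the mean of 13 other atrial genes gave r = 0.41 (exact permutation p = 0.282, adjusted 0.423 over 3 relations) and rho = 0.45 (p = 0.192, adjusted 0.288; n = 10), and r = -0.0091 without replicates 241 and 255. The relation was not established. Replicates 241 and 255 were left out as the farthest from the median of the atrial score. This narrows the range of that score, so the smaller r cannot show that the relation rested on them.

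A second hypothesis was that matrix and fatty acid oxidation genes lie on 1 axis between libraries. Within genotype their scores gave r = -0.68 (exact permutation p = 0.0805, adjusted 0.241) and rho = -0.64 (p = 0.0951, adjusted 0.285; n = 10), and r = -0.25 without replicates 230 and 243. The direction was as the hypothesis needs, but it did not pass the test. These 2 libraries were left out as the farthest from the median of the matrix score, so the smaller r cannot show that the relation rested on them. The relation of Npr1 to endothelial genes was the remaining one of this family (adjusted p = 0.491 for r and 0.373 for rho).

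A further hypothesis was that genes near Npr1 differ because of a strain difference around the targeted locus. Within 5 Mb, 7 of 110 genes (6.36%) had an unadjusted p under 0.05, against 587 of 10653 other genes (5.51%; two-sided Fisher's exact p = 0.672). S100a9 had the smallest p among them (0.00500, log2 difference -0.76). The test, which used gene sums, gave no sign of such a difference. It cannot exclude one in single genes or in single transcripts, such as that of Pogz above.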
